A study of Mus musculus with 36 samples.

How the data were processed

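The series holds RNA sequencing of microglia sorted from the hippocampus of female mice, in 36 libraries of 4 genotypes at 3, 6 and 9 months, with 3 libraries in each of the 12 groups. Per the labels, the cells were sorted as CD11b-positive with low CD45, complementary DNA was made with the SMART-Seq v4 kit, libraries with Nextera XT, and they were sequenced on a NextSeq 500. The labels give each library a genotype, an age and a replicate number and name no batch. All WT and 5xFAD libraries have names beginning with A and all libraries of the Lag3-/- lines names beginning with Q, so Lag3 genotype cannot be separated from anything else that differed between these name series.

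The authors deposited a table of raw counts per gene symbol and a table of RPKM values for the same libraries and symbols. The submitters' processing notes name STAR, Subread, featureCounts and edgeR and the build mm10, without versions, and the annotation is not given in the sources used here. The count table served for every test. The deposited RPKM values were used only to derive the gene length behind each value, which came out equal across the libraries of an age to within 11.28 bases at most. The 3 ages had been counted differently. Of the 30060 symbols, 17108 had a read at 3 months, 27295 at 6 months and 20632 at 9 months. Between 3 and 9 months 33.14% of the symbols read at both had the same gene length, and Selenop had 1600418 reads at 3 months and 0 at 9 months. A symbol with 0 reads in all 12 libraries of an age was therefore treated as not measured at that age and left out of comparisons with that age before p-values were adjusted, which departs from the plan made before the data were examined. Genes encoded by mitochondrial DNA had 0 symbols with a count, so that list could not be read.

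Counts were tested with edgeR 4.0.16 in R 4.3.3. One quasi-likelihood model with a coefficient for each group was fitted to all 36 libraries after filterByExpr (17333 genes kept) and trimmed mean of M values (TMM) normalization, with a common dispersion of 0.1361 and 4.334 prior degrees of freedom. The 23 comparisons were 5xFAD against WT, Lag3-/-;5xFAD against Lag3-/-, Lag3-/- against WT, Lag3-/-;5xFAD against 5xFAD and the difference of the 2 5xFAD effects at each age, the last 3 also as means over the ages, 9 against 3 months in each genotype, and the difference of the 5xFAD effect between these ages. P-values were adjusted by Benjamini-Hochberg within each comparison at a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of F. A gene without a read in a group received a floor of 3 reads over the group.

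The 32 gene lists were fixed before the data were examined. They were the DAM, homeostatic, interferon, class I, class II, lysosome and phagocytosis, complement, cholesterol synthesis, lipid handling, glycolysis, oxidative phosphorylation, ribosomal protein, proliferation, cytokine and NF-kB, immediate early and dissociation, checkpoint and LAG3 ligand, mitochondrial, transgene-related and chromosome 6 neighbour lists and 13 lists of markers of other cell types. Each was tested with camera of limma 3.58.1 with a preset correlation of 0.01, again with an estimated correlation, and with fry, and members past the test were counted. Some lists share members with microglial programmes, for example Siglech with dendritic cells.

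The named genes also follow a rule set in advance. They are Lag3, Apoe, Trem2, Cst7, Itgax, Clec7a, Spp1, P2ry12, Tmem119, Cx3cr1, App, Psen1 and Thy1, then up to 8 genes in each direction with the largest log2 fold changes among those past the test with at least 5 CPM in a compared group and no overlap of libraries between the groups (chance alone separates 3 against 3 libraries in 10% of genes; interactions and means had no overlap condition), and up to 4 members of each list and direction with the smallest adjusted p, or any member of a list with a count of 5 or fewer. Mamdc2, Sox7, Zfp661, Mamld1, Plxnd1, Marchf1 and Oaz1 are given as reads or CPM, and Mbp per library was chosen after its values were seen. Gene positions, length and GC percent come from GENCODE vM21 and the deposited tables, both on mm10.

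The alternatives chosen in advance were relative log expression size factors, no filter on low counts, DESeq2 1.42.0, limma voom with library quality weights, a fit of only the compared groups, a term for library numbers of 500 or more, the replicate number as a block, each library left out in turn, and symbols without reads at an age kept. Added after seeing the data were a fit of each age alone, offsets for gene length and GC (per-library lowess with span 0.3), genes of equal length at 3 and 9 months, and means without 9 months. Figures were drawn with matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6.

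The procedure was tested on simulated counts with 200 changed genes among 15915 for Lag3-/-;5xFAD against 5xFAD at 6 months. edgeR called 13.4% of genes changed 1.5-fold, 41.8% of those changed 2-fold and 75.8% of those changed 4-fold, and 4.4% of its calls were unchanged genes. DESeq2 called 28.4%, 49.3% and 84.8% with 22.3% unchanged among its calls, and limma voom 11.9%, 35.8% and 81.8% with 24.6%. With a length trend added to the simulated counts edgeR made 1960 calls, of which 94.4% were unchanged genes, against 99 calls and 8.08% with length and GC offsets, and the counts in the report carry no such correction unless stated. The spread between replicate libraries, which may include library preparation, exceeded counting error over all genes together. Chi-square per degree of freedom was 20.4 to 247 over 36 pairs.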

Results

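RNA sequencing measured gene expression in microglia sorted from the hippocampus of female mice as CD11b-positive cells with low CD45. The 36 libraries covered 4 genotypes. These were wild type (WT), 5xFAD (which carries human APP and PSEN1 transgenes with familial Alzheimer's disease mutations), Lag3-/- (which lacks the inhibitory receptor LAG3), and Lag3-/-;5xFAD. Each genotype was sampled at 3, 6 and 9 months with 3 libraries per group, which gave 12 groups. Total counts per library were 18767218 to 39753220 at 3 months, 32877558 to 61449890 at 6 months and 21579770 to 48547262 at 9 months. For gene lists the measured members that rose and fell are given, then those that did so adjusted over the list alone (over the list), with camera's adjusted p at the preset and at an estimated correlation. Below, levels are counts scaled to library size (CPM) as mean ± SD, changes are log2 fold changes ± standard error (SE), and n = 3 in each group. Gene positions refer to the mouse build mm10. A gene was called at an edgeR adjusted p under 0.05, and where a value without a library is given, each library was left out alone. For a gene without a read in a group, the fold is a lower bound against a floor of 3 reads over the group, and such floors cover counting error only. Genes with copies or related genes, such as Gm15459, Gm5431 and the H2, ribosomal protein, Klr and Clec genes, may share reads with them. This was not measured, so their levels are uncertain.

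Lag3 (chromosome 6, 124904359 to 124912434) was read in each WT and 5xFAD library, at 38.8 to 107 CPM. The 18 libraries of the 2 Lag3-/- lines held at most 1.279 CPM. At 3 months the Lag3-/- group had 2 Lag3 reads in all and the Lag3-/-;5xFAD group 4, against 6475 in WT and 6282 in 5xFAD. The reads were 72 and 53 at 6 months and 76 and 47 at 9 months. No library had a Lag3 level that went against its label. In 5xFAD against WT the Lag3 change was 0.13 ± 0.40 at 3 months, 0.81 ± 0.40 at 6 months and 0.03 ± 0.40 at 9 months, and none of the 3 passed the test (edgeR adjusted p = 0.946, 0.196 and 0.978). At 6 months all 3 5xFAD libraries lay above all 3 WT libraries, with 87.9 ± 5.09 against 50.2 ± 4.18 CPM.

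**Figure D1:**
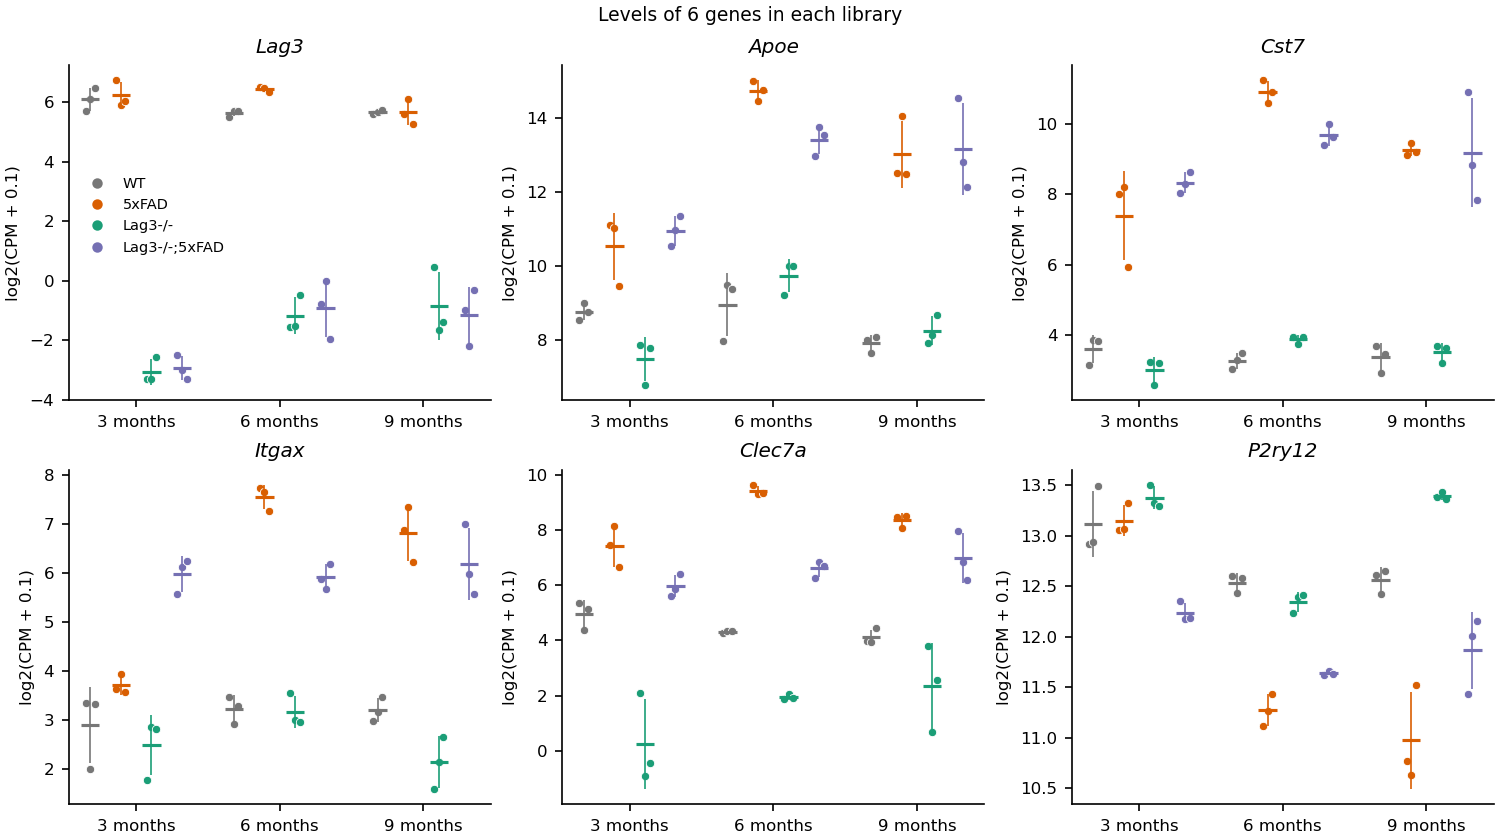
Levels of 6 genes in each of the 36 libraries, as log2 of CPM plus 0.1 (vertical axis) by age and genotype (horizontal axis). Points are libraries, horizontal lines group means and vertical lines 1 SD on that scale. Lag3 was near the bottom of the scale in both Lag3-/- lines, and at 6 and 9 months Apoe, Cst7, Itgax and Clec7a were higher in 5xFAD and Lag3-/-;5xFAD than in WT and Lag3-/-.

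The comparison of 5xFAD with WT asks how hippocampal microglia change as amyloid pathology develops. At 3 months a small set of genes of disease-associated microglia (DAM) and of the interferon response rose. Cst7, an inhibitor of cysteine proteases, stood at 207 ± 127.5 CPM in 5xFAD and 12.3 ± 3.11 in WT (4.08 ± 0.54, edgeR adjusted p = 0.000112). Clec7a, the beta-glucan receptor Dectin-1, rose by 2.53 ± 0.54 (adjusted p = 0.0168), and Baiap2l2 by 7.0 ± 0.91. Of the DAM genes, 12 of 30 rose and 0 fell (25 and 0 over the list, camera adjusted p = 4e-36, or 0.00785 at an estimated correlation). Axl and Ccl6 were among the members that rose. Of the interferon list, 13 of 30 rose and 0 fell (23 and 0 over the list, camera adjusted p = 3.27e-29, or 0.0477 at an estimated correlation). Rsad2 stood at 3.80 ± 0.82, Ifi27l2a at 3.27 ± 0.55 and Mx1 at 3.04 ± 0.73. The class I antigen presentation list had 4 of 16 higher and 0 lower (7 and 0 over the list, camera adjusted p = 2.87e-11, or 0.0446 at an estimated correlation). The 4 were B2m, H2-D1, H2-K1 and H2-M3. Ch25h (cholesterol 25-hydroxylase) rose by 4.73 ± 0.93, Actr3b by 3.87 ± 0.76 and Rab7b by 3.46 ± 0.84. The genes that fell most were Zfp931 (-1.52 ± 0.35), Rusc2 (-1.34 ± 0.33), Tshz1 (-1.33 ± 0.27) and the cation channel gene Trpm2 (-1.30 ± 0.28). Sall3 (-0.98 ± 0.23) was the single homeostatic microglia gene that fell. Apoe stood at 1651 ± 820.1 against 438 ± 68.2 CPM without passing (adjusted p = 0.0526), and Itgax (0.72 ± 0.36), Spp1 (1.62 ± 0.66), P2ry12 (0.01 ± 0.17) and Tmem119 (-0.25 ± 0.14) did not pass either. Of the 14136 genes tested 120 rose and 57 fell. With any 1 library left out the calls of Cst7, Baiap2l2, Axl, Ccl6, B2m and Ifi27l2a held, and that of Clec7a ended without 5xFAD replicate 1 or 2 (2.57 or 2.10) or WT replicate 1, 2 or 3 (2.75, 2.29 or 2.59). The other 13 named calls ended without at least 1 library, among them all 13 without 5xFAD replicate 1 (Ch25h 4.07, Rsad2 3.65, Trpm2 -1.15). The count was 24 or 65 without 5xFAD replicate 1 or 2 and 54, 292 or 55 without WT replicate 1, 2 or 3, 26 in a fit of only the compared groups, 504 with DESeq2 and 680 with limma voom. Scaling by relative log expression (RLE) gave 117 higher and 91 lower.

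At 6 months all 30 genes of the DAM list rose in 5xFAD (camera adjusted p = 6.35e-47, adjusted p = 0.00158 at an estimated correlation). Apoe, a lipid carrier, reached 27650 ± 5160 CPM against 545 ± 256 in WT (5.67 ± 0.59, edgeR adjusted p = 4.97e-08). Cst7 rose by 7.70 ± 0.63, Itgax (the integrin CD11c) by 4.34 ± 0.40, Clec7a by 5.11 ± 0.61, Spp1 (osteopontin) by 6.03 ± 0.77 and Trem2 by 1.37 ± 0.18. Mamdc2 had 15317 reads in 5xFAD and 3 in WT, and Sox7 1759 and 1. The glycoprotein gene Gpnmb (11.13 ± 1.59), Baiap2l2 (9.90 ± 0.88), Ch25h (9.43 ± 1.11) and the heparanase gene Hpse (8.58 ± 0.91) were also among the largest rises. Atp6v0d2, a subunit of the vacuolar proton pump, had no reads in WT and was at least 293.7-fold higher in 5xFAD. Homeostatic genes fell: 0 of 25 rose and 15 fell (0 and 16 over the list, camera adjusted p = 3.16e-12, or 0.032 at an estimated correlation). P2ry12, a purine receptor, went from 5950 ± 373 to 2482 ± 270.3 CPM (-1.26 ± 0.18), Tmem119 changed by -1.30 ± 0.14 and the fractalkine receptor gene Cx3cr1 by -0.91 ± 0.19. Ptger3 (-3.47 ± 0.49), Gpr165 (-3.44 ± 0.64), Slc5a10 (-3.0 ± 0.38), Sema6d (-2.91 ± 0.61) and Hlf (-2.84 ± 0.56) fell most.

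In the interferon list at 6 months 28 of 30 rose and 0 fell (28 and 0 over the list, camera adjusted p = 4.48e-24, or 0.0336 at an estimated correlation). In the class I list 15 of 17 rose and 0 fell (17 and 0 over the list, camera adjusted p = 4.21e-21, or 0.00214 at an estimated correlation). In the class II list 7 of 10 rose and 0 fell (7 and 0 over the list, camera adjusted p = 2.54e-05, or 0.0955 at an estimated correlation). Among its members Cd74, H2-Ab1, H2-Oa and H2-Ob rose. Lysosome and phagocytosis genes such as Npc2, Gusb and Fcgr2b rose (19 of 30 up and 0 down, 21 and 2 over the list, camera adjusted p = 7.65e-13, or 0.00214 at an estimated correlation). The complement list had 9 of 16 higher and 1 lower (9 and 1 over the list, camera adjusted p = 0.00264, or 0.0336 at an estimated correlation). C1qb, C4b and C3 rose and C5ar2 fell, but not without 5xFAD replicate 1, 2 or 3 (-0.74, -0.89 or -0.93) or WT replicate 1 or 3 (-0.71 or -0.84). Cholesterol synthesis genes rose (12 of 21 up and 0 down, 13 and 1 over the list, camera adjusted p = 8.78e-07, or 0.0044 at an estimated correlation), among them Cyp51, Ldlr, Srebf2 and Fdps. In the glycolysis list 10 of 18 rose and 0 fell (12 and 1 over the list, camera adjusted p = 4.94e-11, or 0.00445 at an estimated correlation), with Pkm, Gpi1, Aldoa and Pgk1 up. All 33 ribosomal protein genes rose (camera adjusted p = 5.19e-36, adjusted p = 0.032 at an estimated correlation). Of the oxidative phosphorylation genes 20 of 28 rose and 0 fell (25 and 0 over the list, camera adjusted p = 9.72e-15, or 0.115 at an estimated correlation). Cell cycle genes had 9 of 27 higher and 0 lower (11 and 0 over the list, camera adjusted p = 9.02e-05, or 0.163 at an estimated correlation), including Cdk1, Ccnb2 and Birc5. The lipid handling list had 5 of 18 higher and 2 lower (5 and 2 over the list, camera adjusted p = 0.0163, or 0.0955 at an estimated correlation). The cytokine list had 8 of 27 higher and 2 lower (12 and 2 over the list, camera adjusted p = 0.0268, or 0.568 at an estimated correlation), with Ccl3, Ccl4 and Cxcl16 up and Nfkb1 and Il10ra down. In the checkpoint and LAG3 ligand list Pdcd1 (PD-1), Cd274 (PD-L1) and Lgals3 rose and Vsir and Cd80 fell, of 15 measured (camera adjusted p = 0.555), and the median of the list was -0.11 and its mean 0.77. In all, 1623 of 16355 genes rose and 923 fell, and shorter genes tended to be higher in 5xFAD (Spearman correlation of log2 fold change with gene length -0.32 across 9773 genes, which are not independent replicates). The count was 5474 with limma voom and 4039 in a fit of this age alone, an alternative added after the data were seen.

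At 9 months 3559 of 15663 genes rose and 4069 fell in 5xFAD (quality weights 0.221, 0.387 and 0.579, highest of all 2.95). In the DAM list 28 of 30 rose and 0 fell (28 and 0 over the list, camera adjusted p = 3.99e-19, or 0.0497 at an estimated correlation). In the homeostatic list 0 of 25 rose and 21 fell (1 and 21 over the list, camera adjusted p = 2.97e-08, or 0.122 at an estimated correlation). Apoe stood at 9504 ± 6512 against 241 ± 37.1 CPM (5.30 ± 0.58, edgeR adjusted p = 1.74e-08), and Cst7, Itgax, Clec7a and Spp1 rose by 5.91 ± 0.58, 3.67 ± 0.39, 4.23 ± 0.59 and 6.29 ± 0.79. Without a read in WT, Gpnmb, Mamdc2, Tmem51, Dcstamp and Colec12 were at least 4977-, 3107-, 687.9-, 575.9- and 565.2-fold higher in 5xFAD. P2ry12 fell by 1.54 ± 0.18, Tmem119 by 1.14 ± 0.14 and Cx3cr1 by 1.48 ± 0.19 on the log2 scale. Ptger3 (-6.49 ± 0.64) and Bank1 (-4.50 ± 0.25) fell, and Zfp661 and Mamld1 had 1 read each in 5xFAD against 561 and 419 in WT. Interferon genes rose (27 of 29 up and 0 down, 27 and 0 over the list, camera adjusted p = 2.15e-11, or 0.267 at an estimated correlation). So did class I genes (16 of 17 up and 0 down, 16 and 0 over the list, camera adjusted p = 5.4e-13, or 0.0497 at an estimated correlation) and class II genes (8 of 10 up and 0 down, 8 and 0 over the list, camera adjusted p = 0.000297, or 0.237 at an estimated correlation). Cholesterol synthesis genes had 15 of 21 higher and 2 lower (15 and 2 over the list, camera adjusted p = 0.00022, or 0.0497 at an estimated correlation), led by Msmo1, Dhcr7, Fdps and Insig1. All 33 ribosomal protein genes rose (median 2.78, camera adjusted p = 1.87e-32, adjusted p = 0.0695 at an estimated correlation), as did all 28 oxidative phosphorylation genes (median 2.73, camera adjusted p = 1.45e-24, adjusted p = 0.0695 at an estimated correlation). Immediate early and dissociation response genes fell (0 of 23 up and 12 down, 0 and 12 over the list, camera adjusted p = 0.0339, or 0.884 at an estimated correlation), with Jun, Klf2, Klf4 and Fos among them. Of the 3 transgene-related genes Psen1 changed by -0.84 ± 0.11, Thy1 had 0 reads in WT and 2, 3 and 24 in the 5xFAD libraries (not past the test without replicate 3) and App did not pass (-0.23 ± 0.12, or 0.40 and past the test with the length and GC offsets named below). The transgenes share sequence with these genes, so their counts are uncertain. Log2 fold change and gene length correlated at -0.59 across genes, with a median of 0.93 in the shortest 25% and -0.78 in the longest 25%. With gene length and GC offsets, added after the data were seen, 6326 genes were called and the median of all genes shifted by 0.17.

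Lag3-/-;5xFAD against Lag3-/- gives the 5xFAD effect in Lag3-/- mice. At 3 months among DAM genes 23 of 30 rose and 0 fell (27 and 0 over the list, camera adjusted p = 2.18e-46, or 0.00179 at an estimated correlation), with Cst7 at 328 ± 69.3 against 7.999 ± 1.89 CPM (5.36 ± 0.57, edgeR adjusted p = 1.3e-06), Itgax at 3.45 ± 0.39 and Apoe at 3.44 ± 0.54. Mamdc2 and the antiviral gene Oas2 had no reads in Lag3-/- and were at least 207.1-fold and 128.4-fold higher (Oas2 not past the test without Lag3-/-;5xFAD replicate 2 or any 1 Lag3-/- library), and Hpse (5.91 ± 1.09), Rab7b (5.71 ± 0.98) and Ch25h (5.51 ± 0.99) also rose. P2ry12 changed by -1.14 ± 0.18, and Mzt1 (-1.62 ± 0.18) and Lin7c (-1.31 ± 0.21) fell. At 6 months all 30 DAM genes rose (camera adjusted p = 5.94e-51, adjusted p = 0.00038 at an estimated correlation). Cst7 rose by 5.85 ± 0.58, Apoe by 3.68 ± 0.54, Clec7a by 4.71 ± 0.60, Itgax by 2.75 ± 0.37, Gpnmb by 6.45 ± 1.24, Tmem163 by 7.14 ± 0.82 and Trpm1 by 7.78 ± 1.29. P2ry12 was the single homeostatic gene that fell (-0.71 ± 0.17), but not without Lag3-/- replicate 2 or 3 (-0.68 or -0.67). E2f3 fell by 1.14 ± 0.26, but not without Lag3-/-;5xFAD replicate 2 (-1.03) or Lag3-/- replicate 3 (-0.95), while Tmem119 (-0.30 ± 0.14) and Cx3cr1 (0.18 ± 0.19) did not pass. At 9 months among DAM genes 29 of 30 rose and 0 fell (29 and 0 over the list, camera adjusted p = 1.52e-25, or 0.0369 at an estimated correlation). Hpse, Mamdc2, Igf1 (insulin-like growth factor 1) and Lox (lysyl oxidase), all without reads in Lag3-/-, were at least 2997-fold, 2796-fold, 2668-fold and 898.8-fold higher, and P2ry12 fell by 1.49 ± 0.18. Dnajb9 (-2.12 ± 0.22), Ptger3 (-2.02 ± 0.45) and G2e3 (-1.85 ± 0.24) fell. At 9 months the spread of Lag3-/-;5xFAD was wide, with 872 ± 924 CPM of Cst7, since replicate 1 stood at 1932 CPM and replicates 2 and 3 at 454 and 229.9. The class I list had 9 of 16 higher and 0 lower (12 and 0 over the list, camera adjusted p = 7.54e-14, or 0.0184 at an estimated correlation) at 3 months. At 6 months it had 16 of 17 higher and 0 lower (17 and 0 over the list, camera adjusted p = 5.48e-26, or 0.00038 at an estimated correlation). At 9 months it had 15 of 17 higher and 0 lower (17 and 0 over the list, camera adjusted p = 1.27e-16, or 0.0201 at an estimated correlation). Interferon genes had 20 of 30 higher and 0 lower (26 and 0 over the list, camera adjusted p = 3.11e-24, or 0.0329 at an estimated correlation) at 6 months. Glycolysis genes had 13 of 18 higher and 0 lower (13 and 0 over the list, camera adjusted p = 2.52e-17, or 0.00038 at an estimated correlation) there. Cholesterol synthesis genes had 5 of 21 higher and 0 lower (12 and 0 over the list, camera adjusted p = 6.72e-10, or 0.00038 at an estimated correlation). Of 14136 genes 1156 were called at 3 months, of which 594 fell. Genes that rose and fell numbered 649 and 96 of 16355 at 6 months and 2312 and 1568 of 15663 at 9 months. RLE scaling gave 522 and 165 at 6 months. The 3-month count was 582 or 757 without Lag3-/-;5xFAD replicate 2 or 3 and 307 higher plus 314 lower or 653 without Lag3-/- replicate 1 or 2, and the 6-month count 296 without Lag3-/-;5xFAD replicate 2 and 433, 440 or 369 without Lag3-/- replicate 1, 2 or 3. A fit of only the compared groups gave 2317, 1449 and 1825 genes at 3, 6 and 9 months, fits of each age 1507 and 2006 at 6 and 9 months, limma voom 3360 and 2219 at 3 and 6 months, and DESeq2 1138 at 6 months.

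**Figure D2:**
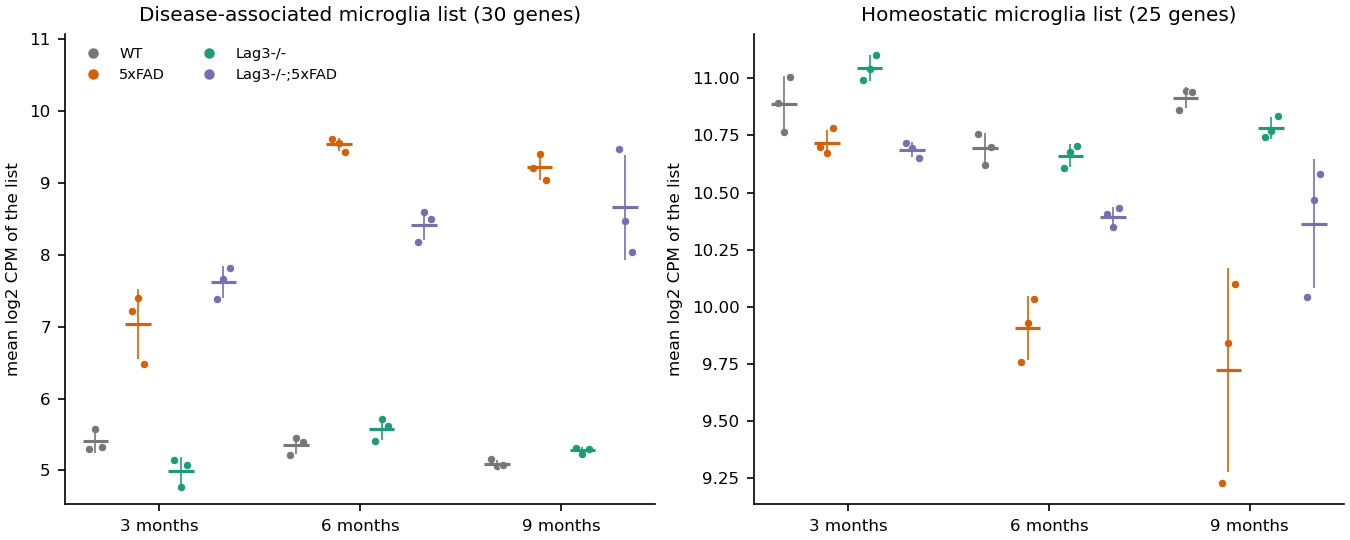
Mean log2 CPM of the DAM list (left, 30 genes) and the homeostatic list (right, 25 genes) in each library, by age and genotype. Points are libraries, horizontal lines group means and vertical lines 1 SD. The DAM mean was higher in 5xFAD and Lag3-/-;5xFAD than in the mice without transgenes at each age, and at 6 months it was lower in Lag3-/-;5xFAD than in 5xFAD.

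Whether loss of Lag3 changes microglia that carry the amyloid load is asked by Lag3-/-;5xFAD against 5xFAD. At 6 months 0 of 30 DAM genes rose and 12 fell (0 and 23 over the list, camera adjusted p = 1.37e-14, or 0.212 at an estimated correlation). Clec7a stood at 98.7 ± 19.9 CPM against 686 ± 93.2 (-2.80 ± 0.55, edgeR adjusted p = 0.00228), Itgax at 60.5 ± 11.2 against 189 ± 31.3 (-1.64 ± 0.35) and Spp1 at 31.7 ± 10.98 against 206 ± 65.4 (-2.70 ± 0.65). Hif1a, Ccl6 and Cd63 fell as well. Apoe (-1.31 ± 0.49, adjusted p = 0.136) and Cst7 (-1.24 ± 0.47, adjusted p = 0.14) did not pass, and Trem2 stood at -0.13 ± 0.18. In the homeostatic list 8 of 25 rose and 0 fell (12 and 0 over the list, camera adjusted p = 8.06e-10, or 0.212 at an estimated correlation). Tmem119 stood at 5471 ± 213 against 2461 ± 213 CPM (1.15 ± 0.14) and Cx3cr1 rose by 0.89 ± 0.19, with Selplg and Txnip, while P2ry12 did not pass (0.36 ± 0.17). Grik4, a kainate receptor subunit, stood at 19.4 ± 0.839 against 0.196 ± 0.157 CPM (6.65 ± 0.72). Gm15459 (4.60 ± 0.47), the collagen hydroxylase gene P4ha2 (4.28 ± 0.61), BC064078 (3.79 ± 0.56), the prostaglandin receptor gene Ptger3 (2.96 ± 0.49), Lyrm7 (2.62 ± 0.39) and Slc5a10 (2.39 ± 0.38) rose. Klrb1b (-5.07 ± 1.48), Clec1a (-4.27 ± 1.10), Atp6v0d2 (-3.98 ± 1.03) and the sorting receptor gene Sorl1 (-3.38 ± 0.79) fell, as did the mannose receptor gene Mrc1 (-3.43 ± 0.94), a marker of macrophages at brain borders. H2-Aa (-3.50 ± 0.94), H2-Eb1 (-3.22 ± 0.96), H2-Ab1 and Cd74 of class II fell, but 5xFAD replicate 2 carried 743 CPM of H2-Aa against 48.0 and 149 in the other 2 libraries. The calls of Clec7a, Itgax, Hif1a, Ccl6, Cd63, Tmem119, Selplg, Txnip, Grik4, Gm15459, P4ha2, BC064078, Ptger3, Lyrm7 and Slc5a10 held with any 1 library left out. Spp1 was not past the test without 5xFAD replicate 1 (-2.58) or Lag3-/-;5xFAD replicate 1 (-2.43), nor Cx3cr1 without 5xFAD replicate 1 (0.78) or Lag3-/-;5xFAD replicate 2 (0.74). Sorl1 was not past it without Lag3-/-;5xFAD replicate 1 or 2 (-3.23 or -3.14), nor H2-Aa without 5xFAD replicate 2 (-1.84) or Lag3-/-;5xFAD replicate 1, 2 or 3 (-3.27, -3.82 or -3.58). The calls of Klrb1b (-6.06 to -4.58) and Atp6v0d2 (-4.41 to -3.46) ended without any 1 of the 6 libraries, and those of Mrc1 (-3.62 to -3.12) and Clec1a (-4.77 to -3.91) without each but 5xFAD replicate 2. In a fit of only the compared groups Apoe (-1.28) and Cst7 (-1.21) passed.

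Other lists at 6 months had few calls in this comparison. Ribosomal protein genes had 0 of 33 higher and 9 lower (0 and 17 over the list, camera adjusted p = 1.86e-10, or 0.592 at an estimated correlation). Oxidative phosphorylation genes had 0 of 28 higher and 4 lower (0 and 13 over the list, camera adjusted p = 4.73e-06, or 0.62 at an estimated correlation). In the border macrophage list 0 of 10 rose and 1 fell (0 and 7 over the list, camera adjusted p = 0.000327, or 0.377 at an estimated correlation). In the interferon list 0 of 30 rose and 0 fell (0 and 0 over the list, camera adjusted p = 0.000842, or 0.812 at an estimated correlation). Lysosome genes had 1 of 30 higher and 3 lower (1 and 7 over the list, camera adjusted p = 0.0155, or 0.592 at an estimated correlation), with Atp6v1a and Lipa and Atp6v0d2 down and Tfeb up, each of them not without at least 1 library (Atp6v1a without 5xFAD replicate 3 (-0.59) or Lag3-/-;5xFAD replicate 1 (-0.52)). Cell cycle genes had 2 of 27 higher and 0 lower (2 and 1 over the list, camera adjusted p = 0.00642, or 0.62 at an estimated correlation), with Mcm5 and Mcm3 up, in each case not without any 1 of the 6 libraries (0.51 to 0.65 and 0.30 to 0.46), while camera ranked the list lower. Of 16355 genes tested 535 rose and 222 fell. RLE scaling gave 412 and 276, and gene length and GC offsets 273 and 274. The count was 254, 496 or 343 without 5xFAD replicate 1, 2 or 3 and 444, 327 or 380 without Lag3-/-;5xFAD replicate 1, 2 or 3, 252 with a term for the library number, 473 with no filter on low counts, 2214 with limma voom and 1231 with DESeq2.

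At 3 months the same comparison gave changes in both directions within the lists. In the DAM list 6 of 30 rose and 4 fell (8 and 4 over the list, camera adjusted p = 0.126). Itgax rose from 13.02 ± 1.84 to 63.9 ± 15.1 CPM (2.29 ± 0.37, edgeR adjusted p = 4.59e-05), and Axl rose with it, while Clec7a (-1.54 ± 0.52) and Ccl6 fell. In the homeostatic list 6 of 25 rose and 6 fell (6 and 8 over the list, camera adjusted p = 0.322), with Cx3cr1 at 0.80 ± 0.19 and P2ry12 at -0.92 ± 0.18. Apoe (0.30 ± 0.49), Cst7 (0.67 ± 0.47) and Tmem119 (-0.09 ± 0.14) did not pass. The semaphorin receptor gene Plxnd1 had 873 reads against 3 in 5xFAD. Grik4 (8.01 ± 0.88), BC064078 (4.06 ± 0.59), Nup210 (3.32 ± 0.68), the fatty acid synthase gene Fasn (3.14 ± 0.51) and the filamin gene Flna (3.07 ± 0.45) rose. Slc36a2, without a read in Lag3-/-;5xFAD, was at least 242.3-fold lower, and Pttg1 (-2.30 ± 0.37), Mrpl32 (-1.78 ± 0.23) and Mzt1 (-1.75 ± 0.18) fell. App stood at 309 ± 23.2 against 153 ± 21.8 CPM (1.02 ± 0.12). In the glycolysis list 7 of 18 rose and 0 fell (7 and 0 over the list, camera adjusted p = 0.0209, or 0.927 at an estimated correlation). In the immediate early list 0 of 23 rose and 5 fell (0 and 5 over the list, camera adjusted p = 0.0481, or 0.977 at an estimated correlation). Of 14136 genes 1666 rose and 1350 fell, and longer genes tended to be higher in Lag3-/-;5xFAD (Spearman correlation 0.56 across genes). The calls of Itgax, Cx3cr1 and P2ry12 held with any 1 library left out, that of Clec7a ended without 5xFAD replicate 1 or 2 (-1.58 or -1.10) or Lag3-/-;5xFAD replicate 1 or 2 (-1.38 or -1.42) and that of Ccl6 without 5xFAD replicate 2 (-0.54) or Lag3-/-;5xFAD replicate 2 (-0.65). With length and GC offsets 1785 genes were called.

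At 9 months 2909 of 15663 genes rose and 2156 fell in Lag3-/-;5xFAD against 5xFAD. Homeostatic genes rose (16 of 25 up and 0 down, 19 and 0 over the list, camera adjusted p = 0.000467, or 0.697 at an estimated correlation). P2ry12 stood at 0.87 ± 0.18, Tmem119 at 0.47 ± 0.14 and Cx3cr1 at 0.75 ± 0.19, and Selplg, Sparc and Siglech were among them. Libraries of the 2 groups overlapped for P2ry12, Tmem119 and Cx3cr1, and the call of Tmem119 ended without 5xFAD replicate 2 (0.32) or Lag3-/-;5xFAD replicate 2 or 3 (0.29 or 0.28) and that of Cx3cr1 without Lag3-/-;5xFAD replicate 2 (0.54). Of the DAM genes 3 of 30 rose and 7 fell (3 and 7 over the list, camera adjusted p = 0.0162, or 0.919 at an estimated correlation). Cd9, Cd63, Ccl6 and Cox6a2 fell and Ctsd and Timp2 rose, while Apoe (0.32 ± 0.49), Cst7 (0.49 ± 0.47), Itgax (-0.57 ± 0.35), Clec7a (-1.17 ± 0.52) and Spp1 (-1.09 ± 0.62) did not pass. Without Lag3-/-;5xFAD replicate 1, which stood apart in the DAM genes, Itgax (-1.11), Clec7a (-1.82) and Spp1 (-2.85) were lower and passed, and Apoe (-0.71) and Cst7 (-0.87) changed sign without passing. Of interferon genes 0 of 29 rose and 11 fell (0 and 12 over the list, camera adjusted p = 0.00272, or 0.933 at an estimated correlation), with Ifi27l2a at -3.06 ± 0.51. Of class I genes 0 of 17 rose and 8 fell (0 and 9 over the list, camera adjusted p = 0.000593, or 0.697 at an estimated correlation). Of the ribosomal protein genes 32 of 33 fell and Rpl4 rose, though not without 5xFAD replicate 1 (0.45) or Lag3-/-;5xFAD replicate 1 (0.34) (camera adjusted p = 4.58e-28, adjusted p = 0.237 at an estimated correlation). Of the oxidative phosphorylation genes 0 of 28 rose and 27 fell (0 and 27 over the list, camera adjusted p = 1.83e-23, or 0.237 at an estimated correlation). Shorter genes tended to be lower in this comparison (Spearman correlation with gene length 0.46 across genes, median -0.53 in the shortest and 0.40 in the longest 25%). Immediate early genes rose (19 of 23 up and 0 down, 21 and 0 over the list, camera adjusted p = 9.86e-06, or 0.814 at an estimated correlation), with Jun, Fos, Dusp1 and Egr1 among them. Cholesterol synthesis genes had 0 of 21 higher and 5 lower (0 and 5 over the list, camera adjusted p = 0.0179, or 0.391 at an estimated correlation). P4ha2, without a read in 5xFAD, was at least 164.1-fold higher, and Grik4 (7.32 ± 0.83), Plxnd1 (6.21 ± 1.09), Ptger3 (5.32 ± 0.64) and Casp8ap2 (3.83 ± 0.36) rose. Clec1b (-3.28 ± 0.77), Rps21 (-2.75 ± 0.33) and Rpl38 (-2.71 ± 0.28) fell. App rose by 0.47 ± 0.12 and Psen1 by 0.48 ± 0.11. A fit of only the compared groups called 1859 genes.

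The effect of Lag3 loss without transgenes is read from Lag3-/- against WT. At 6 months 10 genes rose and 7 fell of 16355 tested, and 791 had an unadjusted p under 0.05. The genes that rose were Grik4 (23.8 ± 8.47 against 0.341 ± 0.298 CPM, 6.14 ± 0.69), Gm15459 (4.67 ± 0.47), BC064078 (4.32 ± 0.58), Lyrm7 (2.57 ± 0.38), the amino acid transporter gene Slc36a1 (2.08 ± 0.23) and Gm5431 (1.92 ± 0.23) among others. Tnfsf13b (BAFF, 0.89 ± 0.17) and Haao (0.87 ± 0.18) rose too, but did not pass without any 1 of the 6 libraries (0.77 to 0.94 and 0.78 to 0.95). Lag3, Pttg1 (-1.96 ± 0.36), Rapgef6 (-1.90 ± 0.20), the sterol desaturase gene Sc5d (-1.52 ± 0.32) and the ganglioside activator gene Gm2a (-1.03 ± 0.17) fell. Of these calls Grik4, BC064078, Lyrm7, Slc36a1, Gm5431, Pttg1, Rapgef6, Sc5d and Gm2a are among the clustered genes given under other observations. Pttg1 was not past the test without Lag3-/- replicate 2 or 3 (-1.85 or -1.89) or WT replicate 2 or 3 (-1.73 or -1.94), Sc5d without Lag3-/- replicate 2 or 3 (-1.38 or -1.36) or WT replicate 1, 2 or 3 (-1.41, -1.63 or -1.55) and Gm2a without Lag3-/- replicate 1 (-1.0). No DAM gene passed at this age. Apoe (0.68 ± 0.49), Cst7 (0.61 ± 0.48) and Itgax (-0.05 ± 0.35) did not pass. Clec7a stood at 3.77 ± 0.252 against 19.8 ± 0.658 CPM (-2.40 ± 0.56, edgeR adjusted p = 0.12), and it passed in a fit of only the compared groups (-2.42). Small shifts of whole lists without called members passed camera, in a comparison where log2 fold change correlated with gene length at -0.49 and with GC at 0.50 across genes. These were for instance the ribosomal protein list (median 0.45, camera adjusted p = 2.42e-17, adjusted p = 0.393 at an estimated correlation) and the class I list (median 0.35, camera adjusted p = 5.96e-06, adjusted p = 0.329 at an estimated correlation). The neuron list (camera adjusted p = 0.00203, adjusted p = 0.573 at an estimated correlation) and the oligodendrocyte list (camera adjusted p = 0.00323, adjusted p = 0.573 at an estimated correlation) ranked lower, and WT replicate 1 held 201.1 CPM of Mbp against 30.7 and 47.0 in replicates 2 and 3. DESeq2 called 47 genes and limma voom 196, and the count was 11, 11 or 10 without Lag3-/- replicate 1, 2 or 3 and 10, 9 or 10 without WT replicate 1, 2 or 3.

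At 3 months 883 of 14136 genes rose and 404 fell in Lag3-/- against WT. Grik4 had no reads in WT and was at least 837.6-fold higher, BC064078 rose by 4.88 ± 0.65, Lyrm7 by 3.77 ± 0.41, Gm5431 by 3.16 ± 0.24 and Ermp1 by 2.18 ± 0.37. Cx3cr1 (0.73 ± 0.19) and App (0.48 ± 0.12) rose too. Klrd1, a natural killer receptor gene without a read in Lag3-/-, was at least 135.6-fold lower. Clec7a fell from 32.2 ± 10.5 to 1.75 ± 2.12 CPM (-4.34 ± 0.65, edgeR adjusted p = 0.000261), and Sorl1 (-2.52 ± 0.78), Pttg1 (-2.45 ± 0.38), Sc5d (-2.40 ± 0.33) and H1f2 (-2.06 ± 0.31) fell. The call of Sorl1 ended without any 1 of the 6 libraries (-2.71 to -2.30). Immediate early genes had 0 of 23 higher and 6 lower (0 and 15 over the list, camera adjusted p = 1.17e-08, or 0.856 at an estimated correlation). Cytokine genes had 0 of 27 higher and 3 lower (0 and 4 over the list, camera adjusted p = 0.00683, or 0.856 at an estimated correlation), with Tgfb1 down. Class I genes had 0 of 16 higher and 4 lower (0 and 5 over the list, camera adjusted p = 0.00875, or 0.856 at an estimated correlation). The neighbours of Lag3 on chromosome 6 had 0 of 36 higher and 4 lower (0 and 9 over the list, camera adjusted p = 0.00151, or 0.443 at an estimated correlation). The count was 430 without Lag3-/- replicate 2 and 843 or 186 without WT replicate 1 or 2, and 373 higher with 358 lower under length and GC offsets. At 9 months 2385 of 15663 genes rose and 2348 fell, with a length trend of -0.51 across genes. BC064078 (5.05 ± 0.63), Lyrm7 (3.66 ± 0.42), Grik4 (3.19 ± 0.61), the chemokine genes Ccl2 (3.01 ± 0.72) and Ccl12 (2.42 ± 0.59), and Plk2 (2.90 ± 0.55) rose. Sorl1 (-5.11 ± 0.86), Fasn (-3.75 ± 0.53), Pcnx3 (-3.80 ± 0.46) and Cad (-3.55 ± 0.51) fell. P2ry12 rose by 0.82 ± 0.17 and Cx3cr1 fell by 0.61 ± 0.19, Itgax changed by -1.04 ± 0.37 (not past the test without Lag3-/- replicate 1 or 2 (-0.87 or -1.08) or WT replicate 2 or 3 (-1.08 or -0.96)), and Clec7a (-1.32 ± 0.54) did not pass. Oxidative phosphorylation genes had 25 of 28 higher and 0 lower (27 and 0 over the list, camera adjusted p = 5.18e-13, or 0.889 at an estimated correlation). Immediate early genes had 14 of 23 higher and 0 lower (15 and 0 over the list, camera adjusted p = 0.0302, or 0.889 at an estimated correlation). With length and GC offsets 3003 genes were called.

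The difference of the 5xFAD effects tests whether the response to the transgenes differs between Lag3-/- and Lag3-intact mice. At 6 months 30 genes had a more positive and 41 a more negative effect in Lag3-/- mice, of 16355 tested. Tmem119 (1.0 ± 0.20, edgeR adjusted p = 0.0234) and Selplg of the homeostatic list, Slc5a10 (2.46 ± 0.51), Slco4a1 (1.92 ± 0.34), Tmem204 (1.83 ± 0.27), Chst7 (1.47 ± 0.24) and Siglece (1.46 ± 0.28) had a more positive effect. Axl (-2.36 ± 0.47), Ccl6 and Cd63 of the DAM list, B2m, Bcl2a1d (-2.45 ± 0.54), Cd52 (-2.20 ± 0.42), Tmsb10 (-2.25 ± 0.44) and Cox7c (-2.04 ± 0.37) had a more negative one. For Apoe (-1.99 ± 0.69), Cst7 (-1.86 ± 0.68), Itgax (-1.59 ± 0.50), Clec7a (-0.40 ± 0.74) and Spp1 (-2.64 ± 0.91) the difference did not pass. In the DAM list 0 of 30 had a more positive effect and 3 a more negative one (0 and 18 over the list, camera adjusted p = 1.91e-17, or 0.1 at an estimated correlation). In the homeostatic list 2 of 25 had a more positive effect and 0 a more negative one (11 and 0 over the list, camera adjusted p = 1.83e-10, or 0.102 at an estimated correlation). In the ribosomal protein list 0 of 33 had a more positive effect and 6 a more negative one (0 and 27 over the list, camera adjusted p = 3.36e-27, or 0.102 at an estimated correlation). Of the named calls only that of Tmem204 held with any 1 library left out. The others ended without 5xFAD replicate 1, with Tmem119 at 0.95 and Axl at -2.33, and most also without other libraries. In a fit of only the compared groups Apoe (-2.00), Cst7 (-1.86), Itgax (-1.58) and Spp1 (-2.65) passed. The count rested on single libraries, at 1 or 24 without 5xFAD replicate 1 or 3, 10, 27 or 13 without Lag3-/-;5xFAD replicate 1, 2 or 3, 22, 36 or 4 without Lag3-/- replicate 1, 2 or 3 and 34, 17 or 9 without WT replicate 1, 2 or 3. DESeq2 gave 374, limma voom 1119 and a term for the library number 108.

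At 3 months the 5xFAD effect differed for 519 of 14136 genes tested, and it was more negative in Lag3-/- mice for 360 of them. Itgax (2.73 ± 0.52, edgeR adjusted p = 0.00257), Axl and Clec7a (2.80 ± 0.81, adjusted p = 0.0497) of the DAM list, Sorl1 (3.71 ± 1.07), Rusc2 (2.34 ± 0.46) and Trpm2 (2.10 ± 0.40) had a more positive effect. P2ry12 (-1.15 ± 0.25) and Hexb of the homeostatic list, Ccl6, Lyrm7 (-2.49 ± 0.53), Mrpl32 (-2.15 ± 0.31), Mzt1 (-2.10 ± 0.25) and Ndfip1 (-1.76 ± 0.23) had a more negative one. Among DAM genes 4 of 30 had a more positive effect and 1 a more negative one (5 and 2 over the list, camera adjusted p = 0.000258, or 0.903 at an estimated correlation). In the glycolysis list 4 of 18 had a more positive effect and 0 a more negative one (4 and 0 over the list, camera adjusted p = 0.000426, or 0.725 at an estimated correlation). The call of Clec7a ended without 5xFAD replicate 1 or 3 (2.76 or 2.50), Lag3-/-;5xFAD replicate 1, 2 or 3 (2.96, 2.89 or 2.54), Lag3-/- replicate 2 or 3 (2.30 or 2.36) or WT replicate 1 or 3 (2.58 or 2.74), and those of Sorl1 (3.50 to 3.90) and Ccl6 (-1.08 to -0.91) without 12 and 5 of the 12 libraries in turn. The count was 63 higher plus 162 lower or 334 without Lag3-/-;5xFAD replicate 2 or 3, 246 or 331 without Lag3-/- replicate 1 or 2 and 319 without WT replicate 1, and 239 with length and GC offsets. At 9 months the numbers were 3460 and 2745 of 15663, with a median log2 difference of all genes of 0.17 and a length trend of 0.60 across genes. Tmem119 (0.67 ± 0.20), Cx3cr1 (1.35 ± 0.27) and App (1.05 ± 0.17) had a more positive effect. Spp1 (-2.42 ± 0.93) and the chemokine genes Ccl12 (-4.75 ± 0.83) and Ccl2 (-4.41 ± 0.98) had a more negative one, and Apoe (-0.05 ± 0.69), Cst7 (0.37 ± 0.68) and P2ry12 (0.04 ± 0.25) did not pass. Without Lag3-/-;5xFAD replicate 1 Apoe stood at -1.04, Cst7 at -0.96 and Spp1 at -4.15, and without 5xFAD replicate 1 Ccl12 at -3.20 and Ccl2 at -2.22. The call of Spp1 ended without 5xFAD replicate 1 or 2 (-2.18 or -2.26), Lag3-/-;5xFAD replicate 2 or 3 (-1.95 or -2.00), Lag3-/- replicate 1 (-1.83) or WT replicate 1 or 2 (-2.21 or -2.23). The oxidative phosphorylation list had 0 of 28 with a more positive effect and 28 with a more negative one (0 and 28 over the list, camera adjusted p = 5.36e-25, or 0.301 at an estimated correlation). The ribosomal protein list had 1 of 33 with a more positive effect and 31 with a more negative one (1 and 32 over the list, camera adjusted p = 1.14e-18, or 0.698 at an estimated correlation). A fit of this age alone gave 4087 genes.

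**Figure D3:**
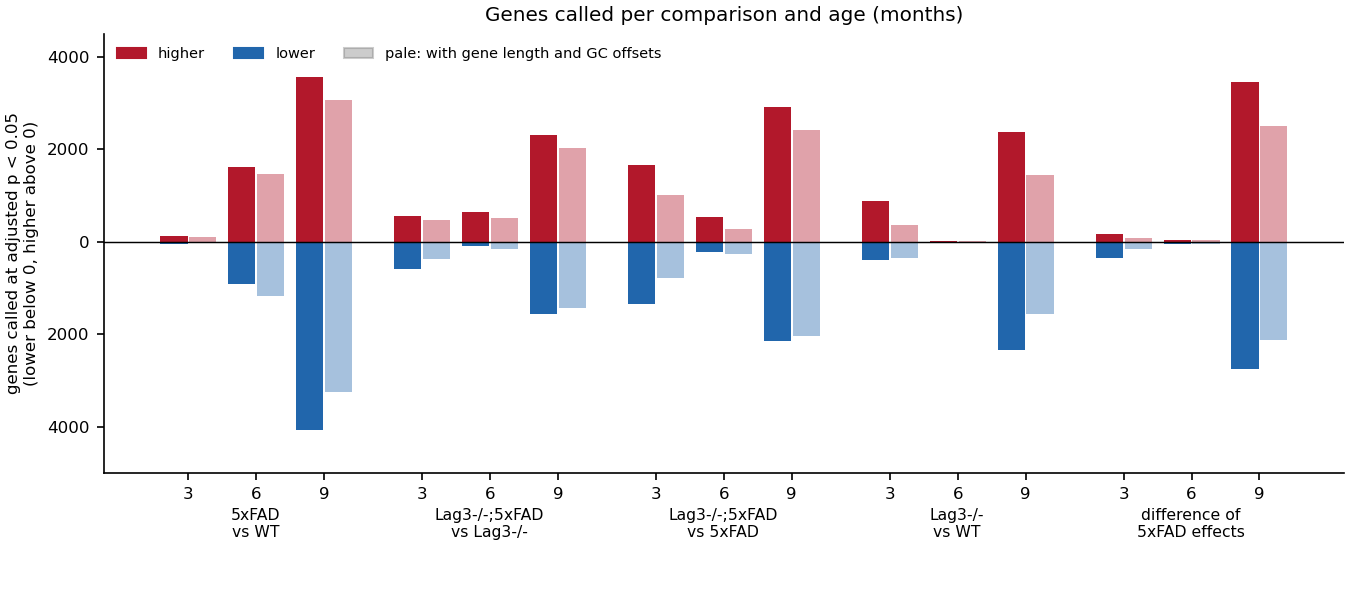
Genes called higher (above 0) and lower (below 0) at an edgeR adjusted p under 0.05, by comparison and age in months. Full colour bars are the tests as reported and pale bars those with gene length and GC offsets, which were added after the data were seen. Lag3-/- against WT at 6 months has the fewest calls, with 10 higher and 7 lower.

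Averaged over the 3 ages, Lag3-/- differed from WT in 645 genes that rose and 416 that fell of 13512 tested. BC064078 (4.75 ± 0.36, edgeR adjusted p = 2.51e-10), Lyrm7 (3.33 ± 0.23), Gm5431 (2.34 ± 0.13), P4ha2 (2.31 ± 0.32) and Slc36a1 (1.30 ± 0.13) rose. Sorl1 (-3.27 ± 0.46), Clec7a (-2.68 ± 0.34), Pttg1 (-1.82 ± 0.21), Cracr2a (-1.72 ± 0.30), Rapgef6 (-1.59 ± 0.11) and Sc5d (-1.58 ± 0.18) fell. Without the 9-month libraries, an alternative added after the data were seen, 14 genes rose and 18 fell, and without Lag3-/- 6-month replicate 1 the count was 706. Lag3-/-;5xFAD differed from 5xFAD in 2559 genes that rose and 1856 that fell, or 1411 and 998 without the 9-month libraries. Grik4 (7.33 ± 0.47), BC064078 (3.51 ± 0.32), Tgtp1 (3.29 ± 0.50) and Ptger3 (2.92 ± 0.31) rose, as did Tmem119 (0.51 ± 0.08) and Cx3cr1 (0.81 ± 0.11). Klrb1b (-3.74 ± 0.81), Clec1a (-3.20 ± 0.61), Clec1b (-2.82 ± 0.44), Pttg1 (-2.53 ± 0.21) and Clec7a (-1.84 ± 0.30) fell, while Apoe (-0.23 ± 0.28), Cst7 (-0.03 ± 0.27), Itgax (0.03 ± 0.20) and Spp1 (-0.74 ± 0.36) did not pass. The mean difference of the 5xFAD effects had 2357 genes above and 1948 below, or 84 and 173 without the 9-month libraries. Tmem119 (0.54 ± 0.11), Cx3cr1 (0.84 ± 0.15) and App (0.65 ± 0.10) lay above and Cox7c (-2.47 ± 0.21), Lsm5 (-2.47 ± 0.31) and Il1rn (-2.26 ± 0.66) below.

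**Figure D4:**
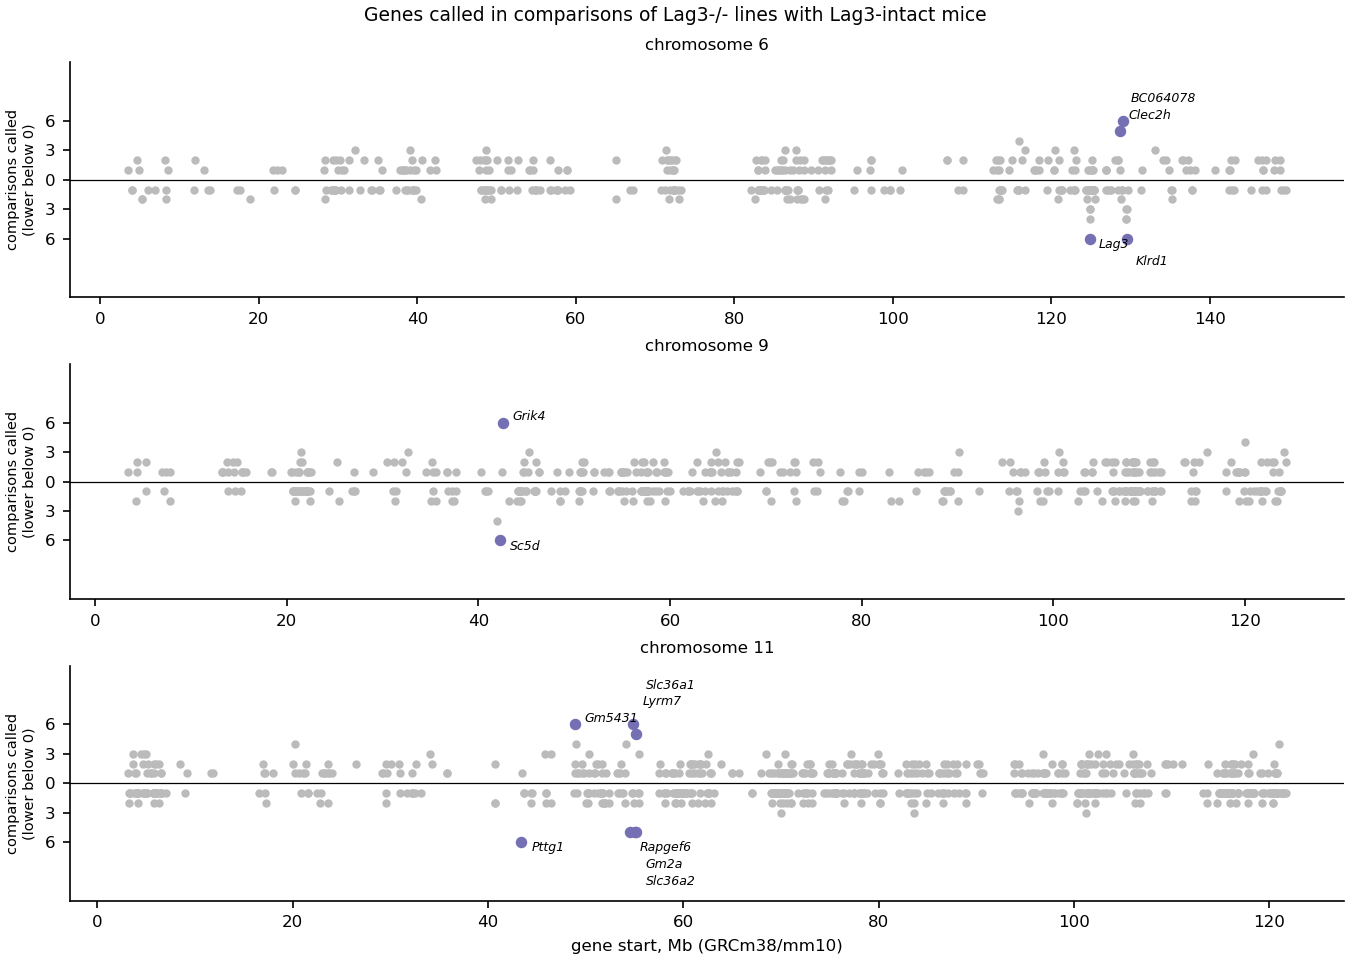
Number of the 6 comparisons of a Lag3-/- line with Lag3-intact mice of the same age in which each gene was called (vertical axis, higher above 0 and lower below 0), by gene start on chromosomes 6, 9 and 11 (horizontal axis, Mb of mm10). Grey points are genes called in 1 to 4 comparisons, and labelled points are genes called in 5 or 6. The labelled genes lie near Lag3 on chromosome 6, near 42 Mb on chromosome 9 and between 43.4 and 55.2 Mb on chromosome 11.

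The effect of age was read from 9 against 3 months within each genotype. In 5xFAD, Apoe went from 1651 ± 820.1 to 9504 ± 6512 CPM (2.52 ± 0.51, edgeR adjusted p = 0.000191, or 1.79 without 9-month replicate 2), and Itgax (3.17 ± 0.38), Spp1 (3.89 ± 0.69), Cst7 (1.59 ± 0.48) and Trem2 (0.73 ± 0.18) rose, while P2ry12 (-2.13 ± 0.18), Tmem119 (-0.50 ± 0.14) and Cx3cr1 (-0.58 ± 0.19) fell. Among DAM genes 24 of 30 rose and 0 fell (25 and 0 over the list, camera adjusted p = 6.51e-11, or 0.117 at an estimated correlation). In the class I list 16 of 16 rose and 0 fell (16 and 0 over the list, camera adjusted p = 3.59e-17, or 0.0154 at an estimated correlation). In Lag3-/-;5xFAD, Apoe (2.55 ± 0.52), Trem2 (0.75 ± 0.18) and Cst7 (1.41 ± 0.48) rose and Cx3cr1 (-0.64 ± 0.19) and Mrc1 (-4.69 ± 1.01) fell, while Itgax (0.31 ± 0.35), Spp1 (1.24 ± 0.62) and P2ry12 (-0.34 ± 0.17) did not pass. Without 9-month replicate 1 Apoe rose by 1.46, and Itgax (-0.29) and Spp1 (-0.59) changed sign. The call of Cst7 ended without Lag3-/-;5xFAD 3-month replicate 1, 2 or 3 (1.3, 1.38 or 1.58) or Lag3-/-;5xFAD 9-month replicate 1 (-0.01), that of Cx3cr1 without Lag3-/-;5xFAD 3-month replicate 1 or 2 (-0.62 or -0.63) or Lag3-/-;5xFAD 9-month replicate 1 (-0.48) and that of Trem2 without Lag3-/-;5xFAD 9-month replicate 1 (0.36). There the DAM list had 16 of 30 higher and 0 lower (22 and 0 over the list, camera adjusted p = 6.28e-09, or 0.28 at an estimated correlation). The class I list had 14 of 16 higher and 0 lower (15 and 0 over the list, camera adjusted p = 9.26e-28, or 0.000542 at an estimated correlation). The lysosome list had 7 of 30 higher and 1 lower (9 and 1 over the list, camera adjusted p = 2.69e-08, or 0.0231 at an estimated correlation). In WT, P2ry12 fell by 0.58 ± 0.17 and Cx3cr1 rose by 0.66 ± 0.19, with Apoe (-0.86 ± 0.49) and Itgax (0.22 ± 0.37) not past the test. Class I genes moved between these differently counted ages in WT too, where H2-T22, H2-D1, Tap2 and Tapbp rose and Psme1 fell (4 of 16 up and 1 down, 7 and 2 over the list, camera adjusted p = 0.00012, or 0.498 at an estimated correlation). The call of Tapbp in WT ended without WT 3-month replicate 2 (0.44) and that of Psme1 with length and GC offsets (-0.04) or without WT 3-month replicate 1 or 2 (-0.67 or -0.47) or WT 9-month replicate 1, 2 or 3 (-0.65, -0.61 or -0.66). In Lag3-/-, Trem2 (0.67 ± 0.18) and Clec7a (2.14 ± 0.64) rose and Cx3cr1 (-0.67 ± 0.19) fell. Calls ended in WT for P2ry12 without WT 3-month replicate 3 (-0.36) or WT 9-month replicate 2 or 3 (-0.51 or -0.59) and for Cx3cr1 without WT 3-month replicate 1 or 2 (0.64 or 0.56) or WT 9-month replicate 2 (0.64). They ended in Lag3-/- for Trem2 without Lag3-/- 9-month replicate 3 (0.42) and for Clec7a without Lag3-/- 3-month replicate 2 or 3 (1.64 or 1.70) or Lag3-/- 9-month replicate 1 (1.15). In 5xFAD they ended for Cst7 without 5xFAD 3-month replicate 3 (1.14) and for Cx3cr1 without 5xFAD 3-month replicate 1 (-0.45) or 5xFAD 9-month replicate 1 (-0.43). Genes that rose and fell numbered 1098 and 1170 in WT, 2910 and 3331 in 5xFAD, 2125 and 2312 in Lag3-/-, and 1009 and 949 in Lag3-/-;5xFAD, of 13586 tested. The count was 1317 or 1067 without WT 3-month replicate 1 or 2 and 1111 without WT 9-month replicate 2 in WT, and 1159 or 943 without Lag3-/-;5xFAD 3-month replicate 1 or 3 and 1083 without Lag3-/-;5xFAD 9-month replicate 1. Marchf1, counted differently between the ages, stood at 234 ± 27.7 CPM at 3 months and 0.0217 ± 0.0376 at 9 months in WT, and Oaz1 at 0.0334 ± 0.0291 and 91.5 ± 5.15. Among genes of equal length at both ages, an alternative added after the data were seen, the counts were 232 and 440 in WT, 1130 and 824 in 5xFAD, 831 and 479 in Lag3-/-, and 378 and 195 in Lag3-/-;5xFAD.

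The 5xFAD effect in Lag3-intact mice was itself compared between 9 and 3 months. Both groups of an age were counted alike, but each age had its own length trend (-0.45 at 3 and -0.59 at 9 months), so a difference in counting need not cancel. The effect was larger at 9 months for Apoe (3.39 ± 0.71, edgeR adjusted p = 0.000594, or 2.63 without 5xFAD 9-month replicate 2), Spp1 (4.67 ± 0.97), Itgax (2.95 ± 0.52), Cst7 (1.83 ± 0.69), Fabp5 (8.31 ± 0.82) and Hpse (7.88 ± 1.47). It was more negative for P2ry12 (-1.55 ± 0.25), Cx3cr1 (-1.25 ± 0.27), Tmem119 (-0.89 ± 0.20) and Ptger3 (-5.72 ± 0.78), and Clec7a (1.70 ± 0.74) did not pass. The call of Cst7 ended without 5xFAD 3-month replicate 3 (1.39), 5xFAD 9-month replicate 1, 2 or 3 (1.87, 1.70 or 1.83), WT 3-month replicate 2 or 3 (1.69 or 1.72) or WT 9-month replicate 1, 2 or 3 (2.0, 1.63 or 1.94). In all, 1833 of 13586 genes had a more positive and 1972 a more negative effect at 9 months, or 873 and 399 among genes of equal length.

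Among markers of other cell types in 5xFAD against WT at 6 months, astrocyte genes Gfap (4.56 ± 0.65) and Aldh1l1 rose and Slc1a3 fell of 12 measured, and Mbp and Mobp rose of 11 oligodendrocyte genes. Cspg4 rose of 6 genes of oligodendrocyte precursors, Flt1 rose and Pecam1 fell of 10 endothelial genes, and Siglec1 rose of 10 border macrophage genes. Ccl5 rose and Il7r fell of 4 T and natural killer cell genes, and Cd22 rose and Cd79b fell of 3 B cell genes. None passed of 14 neuron, 7 mural cell and fibroblast, 7 monocyte, 5 neutrophil, 10 dendritic cell and 5 erythrocyte genes, and camera passed none of the 13 lists of other cell types at this age (smallest adjusted p = 0.189). In Lag3-/-;5xFAD against 5xFAD at 6 months, Mrc1 and Cd22 fell and Mag, Pecam1, Il7r and Cd79b rose. Of 5 measured neutrophil genes, Csf3r, S100a8, S100a9 and Cxcr2 rose in Lag3-/-;5xFAD against Lag3-/- at 9 months, and of 5 erythrocyte genes Hbb-bt, Hbb-bs and Hba-a2 fell in 5xFAD against WT at 9 months. Most of these calls of other cell types ended with a library left out. That of Mbp in 5xFAD ended without 5xFAD replicate 1 (0.64) or WT replicate 2 or 3 (1.33 or 1.49), and that of Mrc1 in Lag3-/-;5xFAD without 5xFAD replicate 1 or 3 (-3.45 or -3.12) or Lag3-/-;5xFAD replicate 1, 2 or 3 (-3.62, -3.47 or -3.32). Those of S100a8, S100a9, Cxcr2, Hbb-bs and Hba-a2 ended without 5 of the 6 libraries in turn. At 9 months Hbb-bs had 0 reads in 5xFAD and 490 in WT, and S100a8 92 in Lag3-/-;5xFAD and 0 in Lag3-/-. Gfap stood at 71.3 ± 42.6 CPM in 5xFAD and 3.06 ± 3.14 in WT at 6 months, and Mbp at 326 ± 315 and 93.0 ± 94.0, against 4320 ± 915 CPM of the microglia gene Cx3cr1 in 5xFAD. The genes encoded by mitochondrial DNA had 0 measured members.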

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

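The tests of border macrophages, of the colony difference without transgenes, of library name series and of handling at 9 months were chosen only after the results were seen, as were the length and GC offsets as a setting.

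Each result here drew attention because a test of the difference between groups called it. The 5xFAD effect differed between Lag3-/- and Lag3-intact mice for 519 genes at 3 months, 71 at 6 months, 6205 at 9 months and 4305 as a mean of the 3 ages. It differed between 9 and 3 months in Lag3-intact mice for 3805 genes. Axl (-2.36), Ccl6 (-1.49) and Cd63 (-1.13) of the DAM list were among the genes at 6 months, with a more negative effect in Lag3-/- mice. Each of these 3 kept its call under the other settings. With 1 library left out, the call of Axl ended without 5xFAD replicate 1 (-2.33), Lag3-/-;5xFAD replicate 1, 2 or 3 (-2.35, -2.28 or -2.51), Lag3-/- replicate 1 or 3 (-2.13 or -2.27) or WT replicate 1, 2 or 3 (-2.24, -2.45 or -2.35). That of Ccl6 ended without 5xFAD replicate 1 (-1.44), Lag3-/-;5xFAD replicate 1 (-1.39), Lag3-/- replicate 3 (-1.36) or WT replicate 2 (-1.45), and that of Cd63 without 5xFAD replicate 1 (-1.10), Lag3-/-;5xFAD replicate 1 or 3 (-1.0 or -1.19), Lag3-/- replicate 1, 2 or 3 (-1.13, -1.13 or -1.04) or WT replicate 1 or 3 (-0.95 or -1.20).

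Other splits of the same libraries were fitted in the same way, 40 for each of these differences with the real one included. At 9 months 1 of 40, the real split, gave 6205 genes or more, and the highest other gave 4209. For the mean of 3 ages, which includes the 9-month libraries, 1 of 40 gave 4305 or more and the highest other gave 137. A share of 1 of 40 is the smallest these splits can give, so chance is made less likely in both but is not excluded. At 3 months 6 of 40 splits gave 519 genes or more and the highest gave 1655, at 6 months 3 of 40 gave 71 or more and the highest gave 432, and for the difference between 9 and 3 months 3 of 40 gave 3805 or more and the highest gave 5142. For these 3 the splits decide nothing about chance. Each other split that gave as many genes exchanged unequal numbers of libraries in the 2 pairs of groups, so that a real difference between groups no longer cancelled. The highest at 3 and 6 months, with several times the real count, points to such a structure of the samples: it exchanged all 3 5xFAD with all 3 Lag3-/-;5xFAD libraries, and 1 WT with 1 Lag3-/- library. The highest for the ages exchanged all 9-month WT and 5xFAD libraries and 1 of each at 3 months.

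At 6 months 12 DAM genes were lower in Lag3-/-;5xFAD than in 5xFAD, with a median log2 change of -1.42. A length or GC trend is argued against as the whole cause: with offsets the median was -1.27 (interquartile range -1.65 to -1.08) and 11 of the 12 calls remained, while Cadm1 went from -0.66 ± 0.17 to -0.39 ± 0.18 (edgeR adjusted p = 0.274) and lost its call through the smaller change. Border macrophages, which a gate on low CD45 would largely remove, stay open. Their list fell from 87.2 to 11.7 CPM and the 12 genes lost 51.3 CPM for each CPM of it. Between the 3 5xFAD libraries, too few to decide, the 12 genes changed by -8.07 ± 6.73 CPM for each CPM of the list. The upper 95% limit was 10.6 with the spread pooled over the 6-month groups. A colony difference present without transgenes is argued against for 11 of the genes by a median of -0.05 in Lag3-/- against WT (range -0.23 to 0.68), but it stays a candidate explanation for Clec7a, which lies in the chromosome 6 stretch given under other observations and was lower without transgenes too, at -2.40 ± 0.56 at 6 months (not past the test) and -4.34 ± 0.65 at 3 months, with a difference of the 6-month effects of -0.40 ± 0.74. For the rest, loss of Lag3 stays open, untested on its own, and cannot be told apart from linked variants or other colony differences acting with the transgenes, since 0 libraries of the Lag3-/- lines have a name in the series of the Lag3-intact mice.

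At 9 months 61 ribosomal protein and oxidative phosphorylation genes had a median log2 change of 2.76 in 5xFAD against WT. Part of it followed gene length, as random lists matched on length and expression had a median of 1.25 and reached 1.91. A length or GC trend is argued against as the whole cause, because with offsets the median was 0.96, 48 members were still higher and matched lists reached 0.48. Handling that differed for the 9-month 5xFAD libraries cannot be told apart from the transgenes at that age, since all 3 libraries of the group would share it and the members were lower in Lag3-/-;5xFAD than in 5xFAD (median -1.67). Amyloid load stays open as an untested biological explanation.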

How the results depend on the processing

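Separate fits of each age, length and GC offsets, genes of equal length, and means without 9 months were chosen after the data were seen. Every alternative set in advance was run. Values below are numbers of called genes unless said otherwise. Where no cause is given, none was tested.

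With RLE size factors all 23 counts stayed within 1.5 times the reported ones. RLE moved the median of all genes by 0.11 (9 against 3 months in 5xFAD) and 0.10 (difference of the 5xFAD effect between 9 and 3 months), and offsets moved it by 0.17 for 5xFAD against WT, -0.14 for Lag3-/-;5xFAD against 5xFAD and -0.16 for the interaction, all at 9 months, and by 0.16 for the difference between 9 and 3 months. With no filter on low counts 22 of 23 stayed within that range, and Lag3-/-;5xFAD against 5xFAD at 6 months gave 473.

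DESeq2 gave 504 for 5xFAD against WT at 3 months, 1931 and 47 for Lag3-/- against WT at 3 and 6 months, and 908 and 374 for the interaction at these ages. At 6 months it gave 1231 for Lag3-/-;5xFAD against 5xFAD and 1138 for Lag3-/-;5xFAD against Lag3-/-. limma voom with quality weights gave, at 3 and 6 months, 680 and 5474 for 5xFAD against WT, 5435 and 2214 for Lag3-/-;5xFAD against 5xFAD, 2735 and 196 for Lag3-/- against WT, 3360 and 2219 for Lag3-/-;5xFAD against Lag3-/-, and 1731 and 1119 for the interaction. For 9 against 3 months it gave 3663 in WT and 3640 in Lag3-/-;5xFAD.

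A fit of only the compared groups, with fewer libraries for the dispersion, gave 26 for 5xFAD against WT at 3 months, 1292 and 1859 for Lag3-/-;5xFAD against 5xFAD at 6 and 9 months, and 2317, 1449 and 1825 for Lag3-/-;5xFAD against Lag3-/- at 3, 6 and 9 months. The interaction gave 408 and 4087 at 6 and 9 months, 9 against 3 months in 5xFAD 3822, and the difference of the 5xFAD effect between these ages 2380. Each age fitted separately gave 4039 for 5xFAD against WT at 6 months, 1656 and 3067 for Lag3-/-;5xFAD against 5xFAD, 27 and 3073 for Lag3-/- against WT, 1507 and 2006 for Lag3-/-;5xFAD against Lag3-/-, and 408 and 4087 for the interaction, at 6 and 9 months. The library-number term gave, at 6 months, 252 for Lag3-/-;5xFAD against 5xFAD, 10 for Lag3-/- against WT and 108 for the interaction. It partly follows Lag3 genotype there, as all Lag3-/- line libraries are past 500.

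Length and GC offsets gave 1785 for Lag3-/-;5xFAD against 5xFAD at 3 months, 731, 3003 and 648 for Lag3-/- against WT at 3 and 9 months and as a mean, and 239 and 2767 for the interaction at 3 months and as a mean. Means without 9 months, from fewer libraries, gave 2409 for Lag3-/-;5xFAD against 5xFAD, 32 for Lag3-/- against WT and 257 for the interaction. For 9 against 3 months, genes of equal length, by construction fewer, gave 672 in WT, 1954 in 5xFAD, 1310 in Lag3-/-, 573 in Lag3-/-;5xFAD and 1272 for the difference of the 5xFAD effect. With symbols without reads at an age kept, as first planned, which adds by construction those counted at 1 age, the counts were 4814 in WT, 6777 in Lag3-/- and 4644 in Lag3-/-;5xFAD.

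With 1 library left out in turn, the lowest and highest counts were 24 to 292 at 3 months for 5xFAD against WT, 254 to 496 at 6 months for Lag3-/-;5xFAD against 5xFAD, 186 to 1791 and 9 to 11 at 3 and 6 months for Lag3-/- against WT, and 582 to 936 and 296 to 647 at these ages for Lag3-/-;5xFAD against Lag3-/-. For the interaction at these ages they were 2.2e+02 (63 higher plus 162 lower) to 463 and 1 to 56. For 9 against 3 months they were 1067 to 2609 in WT and 943 to 1562 in Lag3-/-;5xFAD, and for the mean of Lag3-/- against WT 706 to 1240.

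Replicate numbers were tested for pairing. Of 54 same-numbered pairs of libraries of 2 groups of an age, 14 had deviations from their group means that correlated above 0.1 (range -0.39 to 0.47, median 0.01), and 21 of 54 libraries correlated best with their own number, so the numbers do not pair the libraries as a whole. All 3 pairs were above 0.1 in 2 of the 18 pairs of groups, 6-month 5xFAD with Lag3-/- (0.313, 0.191 and 0.293) and 9-month 5xFAD with Lag3-/-;5xFAD (0.14, 0.233 and 0.12), each with every library correlating best with its own number, a hint from the data and not from the design. With the replicate number as a block, 5xFAD against WT at 3 months gave 202 the interaction at 6 months 87 and Lag3-/-;5xFAD against 5xFAD at 9 months 5024, and all 23 counts stayed within 1.5 times the reported ones.

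Of 365 gene calls checked, 239 held under every alternative run for them, 95 ended under at least 1 setting and 94 without at least 1 library. Reversed were App in 5xFAD against WT at 9 months (0.40 with offsets, edgeR adjusted p = 0.0175, range over alternatives 0.0175 to 0.332) and Cst7 at 9 against 3 months in Lag3-/-;5xFAD (-0.01 without 9-month replicate 1, and -0.01 to 1.86 with any 1 library left out). Of 204 list results past camera as reported, 33 passed in the same direction with an estimated correlation, 202 with RLE, 196 with no filter, 180 with offsets, 194 with the library-number term and 202 with the block, as did 192, with 9 that did not, in fits of only the compared groups and 136, with 3 that did not, in fits of each age. The list that reversed with the library-number term was astrocyte markers in Lag3-/- against WT at 6 months (camera adjusted p = 0.979, range over alternatives 0.0323 to 0.979). With offsets, ribosomal protein genes reversed in Lag3-/- against WT at 9 months (0.218, range 0.0186 to 0.889) and as a mean (0.886, range 0.0146 to 0.955), as did oxidative phosphorylation genes at 9 against 3 months in WT (6.7e-08, range 6.7e-08 to 0.958).

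Depth limits genes with few reads most. Over all genes together, where abundant genes weigh most, the spread between replicate libraries exceeded counting error, untested for genes with few reads. In the simulated counts, with 3 libraries per group, edgeR called 13.4% of genes changed 1.5-fold.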

Other observations

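Both tests of the recurrent genes below were chosen after the result was seen, the splits of the libraries before.

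Besides Lag3, 12 genes were called in the same direction in 5 or 6 of the 6 comparisons of a Lag3-/- line with Lag3-intact mice of the same age. On chromosome 11 these are Pttg1, Gm5431, Lyrm7, Rapgef6, Gm2a, Slc36a2 and Slc36a1, between 43.42 and 55.2 Mb of mm10. BC064078, Klrd1 and Clec2h lie on chromosome 6 between 124.9 Mb, where Lag3 starts, and 129.6 Mb, and Sc5d and Grik4 on chromosome 9 between 42.25 and 42.52 Mb. With the calls of each comparison shuffled over genes, the highest of 200 shuffles gave 2 such genes. Of the 12 genes 100% had another of them within 10 Mb, against a median of 0 and at most 66.7% in 10000 random draws of as many tested genes (permutation test, p = 0.0001, the smallest the draws can give). A candidate explanation is linked segments of another strain or colony in the Lag3-/- lines. Rapgef6 (-0.04), Gm2a (0.81) and Slc36a2 (2.05) were not called lower in Lag3-/-;5xFAD against 5xFAD at 9 months. Changed transcription next to the knockout allele is argued against for the set, as 0 of the 12 lie within 1 Mb of Lag3. At 4 or more of the 6 there were 31 genes besides Lag3, 61.3% with another within 10 Mb, a share the random draws reached.

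Each comparison of 2 groups has 10 library splits, too few for a share under 0.05, and only the real one gave as many genes. In 5xFAD against WT the real counts at 3, 6 and 9 months were 177, 2546 and 7628, and the highest other splits gave 1, 0 and 3. In Lag3-/-;5xFAD against 5xFAD they were 3016, 757 and 5065, with 0, 0 and 429. For Lag3-/- against WT the counts were 1287, 17 and 4733, with 1, 0 and 9, and for Lag3-/-;5xFAD against Lag3-/- 1156, 745 and 3880, with 0, 0 and 34. From 3 to 9 months 2268 genes differed in WT, 6241 in 5xFAD, 4437 in Lag3-/- and 1958 in Lag3-/-;5xFAD, with 1, 21, 2 and 0. For means over the ages 40 splits were fitted. Lag3-/-;5xFAD against 5xFAD gave 4415 genes with 1797 in the highest other split, and Lag3-/- against WT 1061 with 391.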
